A study of Solanum lycopersicum with 27 samples.

How the data were processed

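Gene expression was measured by RNA sequencing of total RNA from tomato fruits, in 27 libraries of 9 groups with 3 replicates each. Per the labels, all plants were of the cultivar Ailsa Craig, without treatment, and the groups were set by genotype and by fruit age in days post anthesis. Groups and replicate numbers were taken from the sample titles, and all columns of the table could be tied to 1 sample by name. The authors deposited 1 table of FPKM values (fragments scaled by gene length and by the mapped fragments of the library) with 1 column per library, so that replicates were not pooled. Trimmomatic, STAR 2.5.4b, RSEM and DESeq2 are named, per the submitters' processing notes, without their role or order. The genome build, the annotation and any further scaling between libraries are not given in the sources used here. FPKM removes differences in total signal but not in its make-up, so that when a few genes take a larger share, all other genes read lower.

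The depth of each library is unknown. Low values were examined for steps of single reads by their ratio to replicate 1 of WT at 25 dpa in the other 26 libraries. The commonest step held at most 3.46% of the low genes of a library, so read numbers could not be recovered and no count test was used. Precision therefore rests on the spread between replicates alone. Comparison of all columns found 0 identical pairs of libraries.

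Of 34075 genes, 18906 with at least 1 FPKM in at least 3 libraries were kept. Values were taken as log2(FPKM + 1), and a log2 change on this scale understates the change of genes near or below 1 FPKM. A difference between 2 such changes can therefore be too large or too small. A linear model with 1 mean per group was fitted to all 27 libraries with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a trend of variance with expression. The groups thus share 1 estimate of the spread, into which replicate 3 of dml2-3 at 25 dpa enters. P-values were adjusted by the Benjamini-Hochberg method over the genes kept, and genes with adjusted p under 0.05 were called. In total 16 contrasts were drawn from this fit: WT between stages, each mutant against WT at its stage, the double mutant against each single mutant, the departure of the double mutant from the sum of the single changes, dml2-3 against the double mutant, each of these genotypes between stages, and the change of their difference from WT with stage. The groups, contrasts, tests and the alternatives, other than those named below as added, were fixed before the data were examined.

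The fit was tested on simulated data with the 18906 genes, for the comparison of dml2-3 with WT at 34 dpa. At each of the changes 0.5, 1, 2 and 4 on the log2 scale, 50 genes were changed. Of these, 74%, 90%, 98% and 100% were recovered, and 12 of the 193 calls were false. Recovery was not broken down by expression level, so these shares do not describe genes of low expression. Far fewer genes were changed than the 14175 called in the real comparison, so the shares do not describe that setting either.

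The identifiers in the table carry no names. None of the 34075 identifiers, 0 with and 0 without their version number, was found among the 41476 genes of the reference table (RefSeq, assembly SLM_r2.1), so the files do not pair identifiers with names. The rule for named genes asked for the mutated genes, for members of fixed gene lists, and for the called genes with the largest changes among those with a name, a mean of at least 10 FPKM in the higher group and no overlap between libraries. The first 2 parts could not be filled. The transcripts of the mutated genes were therefore not identified and do not check the labels here, and tests of gene lists, markers of other fruit tissues included, are not reported, nor are their alternatives. Lists drafted with pairs of identifiers and names remembered from outside these sources, and tests made with them, were left out, since no source used here backs those pairs. Under the rest of the last part, without the condition on names, the 2 largest rises and the 2 largest falls in WT between stages were taken and followed through all comparisons.

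Levels are given as mean ± SD of FPKM. Ripening-risen and ripening-fallen genes were those called in WT at 2-fold or more both as deposited and with size factors. The slope of the mutant stage change on the WT stage change was taken over genes called in WT, and its SD over the 9 pairs of 1 mutant library from each stage. Correlations and covariances of log2 differences between mutants were set beside 100 simulated sets of unchanged groups with the same controls, and overlaps of calls beside those of independent lists. Shares of the 100 most abundant genes and numbers of genes at 1 FPKM or more were compared by two-sided exact permutation tests over the 20 assignments of 6 libraries.

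Alternatives were a pseudocount of 0.1, no filter beyond 1 library above 0, a mean of at least 5 FPKM, division by median-of-ratios size factors, rescaling to TPM, quantile normalization, no trend in the variance, a fit to the compared groups only, at least 2-fold change, the replicate number as a block, and leaving out each library in turn. Fits without replicate 3 of dml2-3 at 25 dpa, or without that group, in comparisons that do not use it, and counts of genes called in the same direction in dml2-3 and the double mutant under other scalings, were added after the data were seen. The slope without that replicate over the genes of the full fit, and mutants simulated without a difference from WT at 34 dpa, were also added then.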

Results

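RNA sequencing of tomato (Solanum lycopersicum, cultivar Ailsa Craig) fruits was examined in 27 libraries that fell into 9 groups of 3. Wild type (WT), the mutant dml2-3 and the double mutant rin/tdr4-1 were each sampled at 25 and at 34 days post anthesis (dpa). The single mutants rin-1, tdr4-1 and nor-1 were sampled at 34 dpa only. By the labels, 34 dpa was the breaker stage, at which the first ripening colour shows. DML2 is a DNA demethylase, RIN and TDR4 are MADS-box transcription factors, and NOR is a NAC transcription factor. The series sets out to ask how MADS-box factors take part in the epigenetic control of ripening. Each library was represented by 1 FPKM value for each of 34075 genes, and 18906 genes with enough signal were tested. FPKM values keep no read numbers, so the depth of each library is unknown. The FPKM columns summed to between 863193 and 1122755. The labels do not say that replicates came from separate plants, so p-values measure only the spread between libraries.

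Fruit of WT moved far along the first principal component between the stages, and fruit of dml2-3 and of the double mutant did not. This component held 46.2% of the variance. WT at 34 dpa (101.8 to 109.5) and tdr4-1 (105.2 to 108.4) lay at one end. The 3 groups sampled at 25 dpa, dml2-3 at 34 dpa and the double mutant at 34 dpa all lay between -73.9 and -47.1. The nor-1 libraries lay at 62.3 to 64.1 and the rin-1 libraries at 14.3 to 14.97. The third component held 11.5% of the variance. On it the double mutant lay at -44.94 to -43.27 at 25 dpa and at 27.02 to 27.66 at 34 dpa. WT lay there at -57.25 to -53.96 at 25 dpa and at 4.19 to 8.08 at 34 dpa. In dml2-3, replicates 1 and 2 at 25 dpa (53.01 and 51.66) lay near the 34 dpa libraries (51.82 to 53.44), and replicate 3 at 21.29. Libraries of a group correlated with r of at least 0.981 across genes in 8 of the 9 groups. In dml2-3 at 25 dpa, replicate 3 correlated with the other replicates at 0.916 and 0.917.

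**Figure D1:**
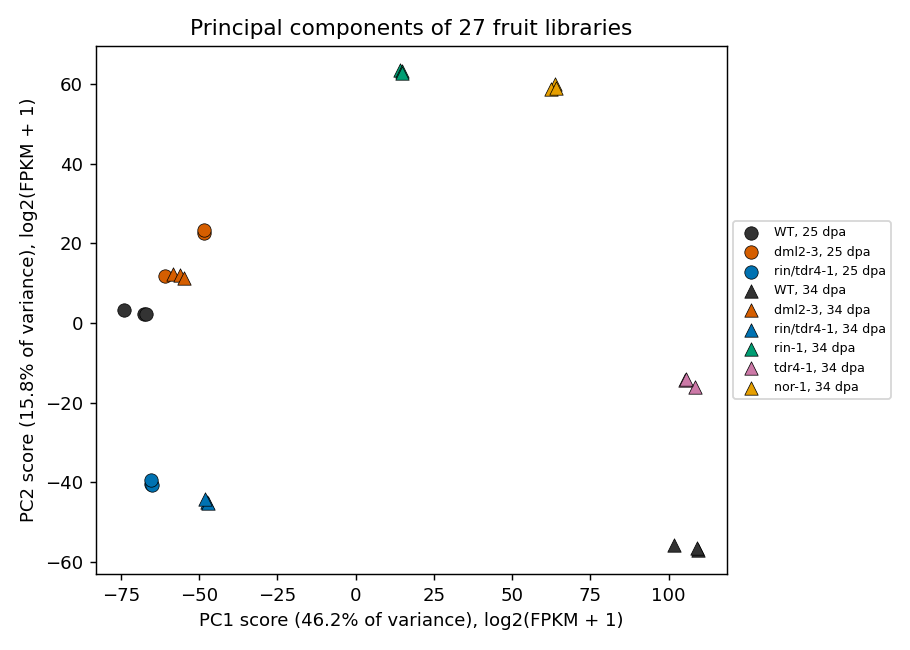
Scores of the 27 libraries on the first (46.2% of variance) and second (15.8%) principal components of log2(FPKM + 1), with circles for 25 dpa, triangles for 34 dpa and 1 colour per genotype. WT moves from -73.9 to -67.1 at 25 dpa up to 101.8 to 109.5 at 34 dpa on the first component, while dml2-3 and rin/tdr4-1 stay below -47.

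Normal ripening was addressed by comparing WT fruit at 34 dpa with WT fruit at 25 dpa, which also differ in age. The gene Solyc10g080210.2 rose from 2.53 ± 0.502 FPKM to 7755 ± 589 FPKM (mean ± SD, n = 3 here and for every FPKM below), a log2 change of 11.11 (SE 0.55, limma adjusted p = 5.76e-14). Solyc08g066240.3 rose from 2.14 ± 0.235 to 2417 ± 248 FPKM, a log2 change of 9.59 (SE 0.25, adjusted p = 1.04e-18). Solyc07g054310.3 fell from 912 ± 103 to 0.763 ± 0.679 FPKM, a log2 change of -9.10 (SE 0.30, adjusted p = 8.07e-17). Solyc01g086920.3 fell from 335 ± 7.14 to 0.377 ± 0.306 FPKM, a log2 change of -7.95 (SE 0.53, adjusted p = 8.81e-12). These 4 genes are the 2 largest rises and the 2 largest falls in WT, and their identifiers are not paired with names in the files used here.

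Of the tested genes, 14555 were called between the WT stages, 2899 of them higher and 11656 lower at 34 dpa. The median gene changed by -0.51 on the log2 scale, and by -0.039 after division by size factors. With size factors, 6759 genes were higher and 7354 lower, and with quantile scaling 7823 were higher and 6044 lower, so the balance of rises and falls depended on the scaling. Genes called at 2-fold or more under both FPKM as deposited and size factors comprised 1030 risen and 3723 fallen genes. These are called the ripening-risen and the ripening-fallen genes here. The names mark only a change in WT between stages that differ in fruit age as well as in ripening, so they do not tie a gene to ripening. The groups were defined after the data were seen. Their median log2 changes in WT were 1.69 and -2.17.

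**Figure D2:**
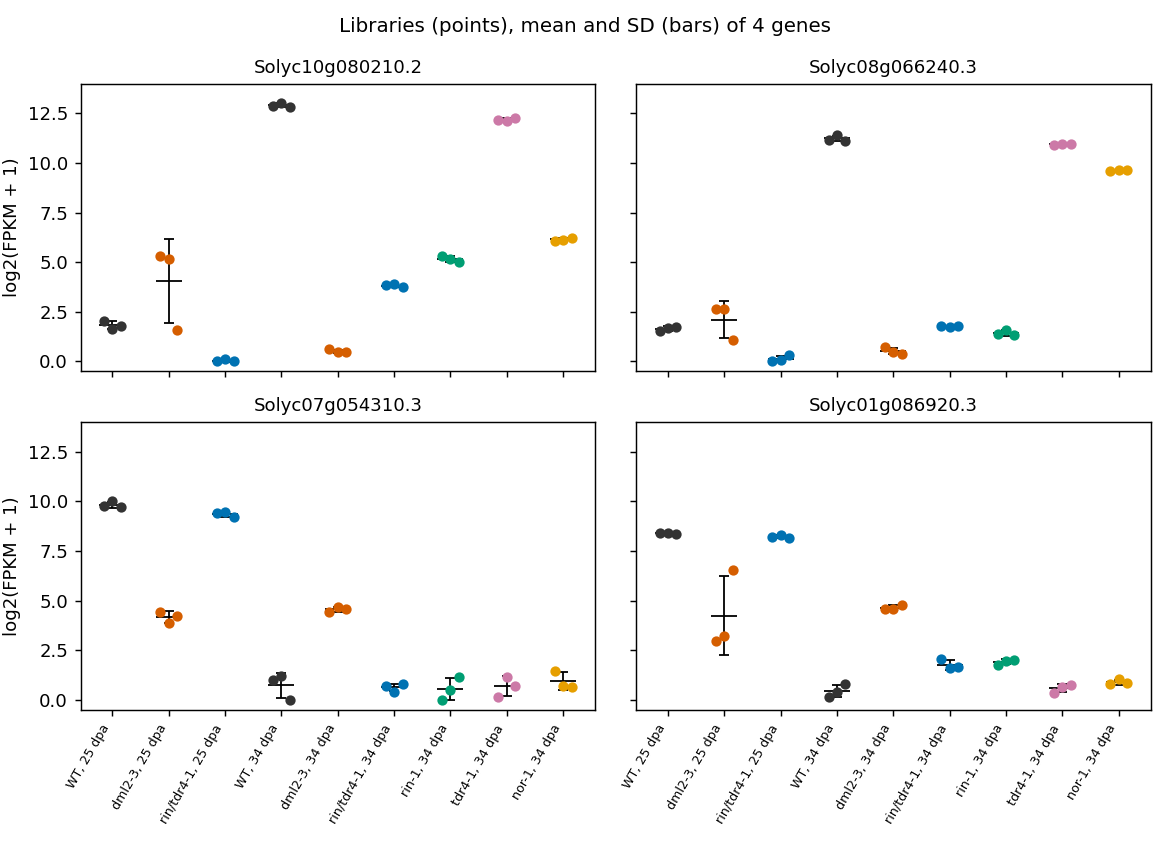
log2(FPKM + 1) of 4 genes in every library (points), with the mean and SD of the log2 values of each group of 3 libraries (horizontal and vertical bars). The upper genes, Solyc10g080210.2 and Solyc08g066240.3, are high in WT and tdr4-1 at 34 dpa and below 1 FPKM in dml2-3 at 34 dpa, and the lower genes, Solyc07g054310.3 and Solyc01g086920.3, stay at 22.6 and 24.0 FPKM in dml2-3 at 34 dpa.

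The effect of dml2-3 at the breaker stage was addressed against WT at 34 dpa. Both genes with the largest rises in WT were near 0 in the mutant. Solyc10g080210.2 was at 0.427 ± 0.0723 FPKM, a log2 difference from WT of -12.41 (SE 0.55, limma adjusted p = 7.87e-15). Solyc08g066240.3 was at 0.43 ± 0.166 FPKM, a difference of -10.73 (SE 0.25, adjusted p = 1.26e-19). The falling genes were higher than in WT, with Solyc07g054310.3 at 22.6 ± 2.37 FPKM (log2 difference 3.83, SE 0.30, adjusted p = 1.95e-10) and Solyc01g086920.3 at 24.0 ± 2.05 FPKM (4.20, SE 0.53, adjusted p = 2.65e-07).

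Of the 1030 ripening-risen genes, 942 were lower in dml2-3 than in WT and 26 were higher, with a median log2 difference of -1.80. Of the 3723 ripening-fallen genes, 3264 were higher and 53 lower, with a median of 1.62. With size factors, 982 ripening-risen genes were lower and 3090 ripening-fallen genes were higher. These groups were chosen with the WT libraries at 34 dpa that also serve as the control here and for the other mutants, which favours opposite signs. Over all tested genes, 14175 were called, 10778 higher and 3397 lower, about a median of 0.42 (0.028 with size factors). With size factors 7204 were higher and 6552 lower, and with quantile scaling 6460 were higher and 7138 lower.

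The double mutant rin/tdr4-1, mutated in both MADS-box genes by its label, was compared with WT at 34 dpa. Solyc10g080210.2 reached 13.1 ± 0.788 FPKM, a log2 difference from WT of -9.10 (SE 0.55, limma adjusted p = 2.12e-12), and Solyc08g066240.3 reached 2.41 ± 0.0755 FPKM, a difference of -9.47 (SE 0.25, adjusted p = 1.76e-18). Solyc07g054310.3 had fallen to 0.547 ± 0.208 FPKM, which did not differ detectably from WT (-0.11, SE 0.30, adjusted p = 0.752). Solyc01g086920.3 was at 2.45 ± 0.618 FPKM, above WT by 1.33 (SE 0.53, adjusted p = 0.0261). That call ended with size factors (1.07, adjusted p = 0.0825) and quantile scaling (0.58, adjusted p = 0.375). It also ended without replicate 1 of WT (1.19, adjusted p = 0.0801), replicate 2 of WT (1.31, adjusted p = 0.0555) or replicate 1 of the double mutant (1.19, adjusted p = 0.0789), and over the alternatives its adjusted p ran from 1.64e-08 to 0.375. With a pseudocount of 0.1 the difference was 2.61.

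In the double mutant, 903 of the ripening-risen genes were lower than in WT and 38 higher (median -1.47), and 3072 of the ripening-fallen genes were higher and 95 lower (median 1.45). With size factors these counts were 960 lower and 21 higher, and 2759 higher and 191 lower. In total 14462 genes were called, 11585 higher and 2877 lower, about a median of 0.51 (0.041 with size factors). With size factors 6964 were higher and 6438 lower, and with quantile scaling 6355 were higher and 6810 lower.

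Each single mutant was likewise compared with WT at 34 dpa. In rin-1, Solyc10g080210.2 was at 34.8 ± 3.52 FPKM (log2 difference -7.76, SE 0.55, limma adjusted p = 3.78e-11) and Solyc08g066240.3 at 1.71 ± 0.275 FPKM (-9.80, SE 0.25, adjusted p = 8.81e-19). Of the ripening-risen genes 773 were lower and 89 higher in rin-1 than in WT (median -1.12), and of the ripening-fallen genes 3032 were higher and 42 lower (median 1.31). Solyc07g054310.3 was at 0.53 ± 0.612 FPKM (adjusted p = 0.593). Solyc01g086920.3 was at 2.78 ± 0.314 FPKM, higher than in WT by 1.48 (SE 0.53, adjusted p = 0.0172), a call that ended with quantile scaling (0.96, adjusted p = 0.141) and without replicate 1 of WT (1.33, adjusted p = 0.0586), within a range over the alternatives of 4.28e-09 to 0.141. With a pseudocount of 0.1 it was 2.80. Over all genes 12687 were called, 8734 higher and 3953 lower, about a median of 0.23 (0.021 with size factors). With size factors 6587 were higher and 6259 lower, and with quantile scaling 5355 were higher and 7509 lower.

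In tdr4-1, both genes with the largest rises in WT were abundant. Solyc10g080210.2 was at 4695 ± 220 FPKM (log2 difference -0.72, SE 0.55, limma adjusted p = 0.334) and Solyc08g066240.3 at 1959 ± 26.9 FPKM (-0.30, SE 0.25, adjusted p = 0.385). These 2 results rested on 1 library of another group. Without replicate 3 of dml2-3 at 25 dpa, which widens the shared estimate of the spread, the adjusted p was 7.09e-07 for the first gene (7.09e-07 to 0.478 over the alternatives) and 0.00832 for the second (0.00832 to 0.628), with the same log2 differences. The first was also called in a fit to the WT and tdr4-1 libraries alone (adjusted p = 0.00752). Solyc07g054310.3 (0.67 ± 0.566 FPKM) and Solyc01g086920.3 (0.503 ± 0.201 FPKM) were both below 1 FPKM, as in WT, with adjusted p of 0.938 and 0.885. Among the ripening-risen genes 378 were lower and 138 higher in tdr4-1 (median -0.18), and of the ripening-fallen genes 1125 were higher and 226 lower (median 0.16). The comparison called 6840 genes, 2550 higher and 4290 lower. With size factors 3663 were higher and 3105 lower. At 2-fold or more, 852 genes were called, 675 higher and 177 lower.

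In nor-1, the rising genes differed from WT by unequal amounts. Solyc10g080210.2 was at 69.7 ± 4.21 FPKM (log2 difference -6.78, SE 0.55, limma adjusted p = 5.38e-10), while Solyc08g066240.3 was at 788 ± 17.6 FPKM (-1.61, SE 0.25, adjusted p = 7.68e-06). Solyc07g054310.3 (0.987 ± 0.688 FPKM, adjusted p = 0.585) and Solyc01g086920.3 (0.843 ± 0.181 FPKM, adjusted p = 0.493) were below 1 FPKM on average. The last gene was called higher, by 0.44 with adjusted p = 0.00844, without replicate 3 of dml2-3 at 25 dpa (0.00841 to 0.835 over the alternatives). Ripening-risen genes were lower in 708 cases and higher in 133 (median -0.92), and of the ripening-fallen genes 2441 were higher and 131 lower (median 0.73). In total 11589 genes were called, 6269 higher and 5320 lower. With quantile scaling 4918 were higher and 7152 lower.

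**Figure D3:**
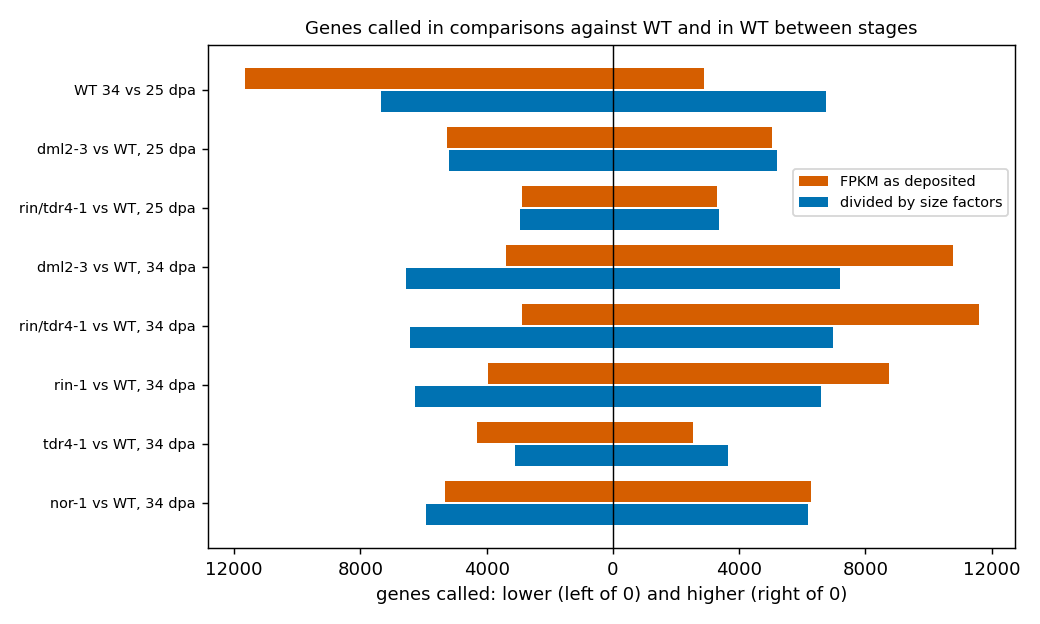
Numbers of genes called lower (left of 0) and higher (right of 0) in WT between the stages and in each mutant against WT, from FPKM as deposited and after division by size factors. In WT the lower calls number 11656 with FPKM as deposited and 7354 with size factors, and in tdr4-1 at 34 dpa the calls are fewest among the mutants at that stage (6840).

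The double mutant was set against each single mutant at 34 dpa. Solyc10g080210.2 was lower in rin/tdr4-1 than in rin-1 by -1.34 on the log2 scale (SE 0.55, limma adjusted p = 0.0344), and lower than in tdr4-1 by -8.38 (SE 0.55, adjusted p = 7.61e-12). Solyc08g066240.3 was lower than in tdr4-1 by -9.17 (SE 0.25, adjusted p = 3.69e-18), and its difference from rin-1 was 0.33 (SE 0.25, adjusted p = 0.236). Of the ripening-risen genes 454 were lower and 283 higher in the double mutant than in rin-1, and 807 were lower and 65 higher than in tdr4-1. Of the ripening-fallen genes 1648 were higher and 1102 lower than in rin-1, and 2783 were higher and 337 lower than in tdr4-1. With size factors the ripening-fallen genes were nearly balanced against rin-1, at 1331 higher and 1305 lower, and not against tdr4-1, at 2357 higher and 558 lower. In total 13146 genes were called against rin-1, 9236 higher and 3910 lower, and 14999 against tdr4-1, 12185 higher and 2814 lower. With size factors the splits were 6261 higher and 6032 lower, and 6855 higher and 6723 lower, and the medians went from 0.26 and 0.57 to 0.014 and 0.031.

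The calls for the first gene against rin-1 and for Solyc01g086920.3 against tdr4-1 (1.19, SE 0.53, limma adjusted p = 0.0431) ended when any 1 of the 6 libraries compared was left out. The first call also ended with a pseudocount of 0.1 (-1.40, adjusted p = 0.0541) and with TPM (-1.14, adjusted p = 0.0605), and the second without a filter on low values (1.19, adjusted p = 0.059), with size factors (0.86, adjusted p = 0.158) and with quantile scaling (0.54, adjusted p = 0.413). The second difference was 2.12 with a pseudocount of 0.1. With 1 library left out, the values ran from -1.42 to -1.27 for the first and from 1.05 to 1.28 for the second. Their adjusted p ran from 1.08e-11 to 0.08 and from 8.34e-08 to 0.413 over the alternatives. Without replicate 3 of dml2-3 at 25 dpa, which enters only the shared spread, Solyc08g066240.3 was called higher than in rin-1 (adjusted p = 0.00181, 0.00181 to 0.76 over the alternatives), as it was in a fit to these 2 groups alone (adjusted p = 0.0122).

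Whether the single changes added up to the double change was tested as the double mutant minus rin-1 minus tdr4-1 plus WT. For Solyc10g080210.2 this difference was -0.62 (SE 0.77, limma adjusted p = 0.495), and for Solyc08g066240.3 it was 0.63 (SE 0.35, adjusted p = 0.115). Both were called without replicate 3 of dml2-3 at 25 dpa, with adjusted p = 0.000136 (0.000136 to 0.661 over the alternatives) and adjusted p = 0.000113 (0.000113 to 0.395). Both were also called in a fit to the 4 groups alone (adjusted p = 0.000493 and 0.000359), and the second with TPM (0.79, adjusted p = 0.0423). The ripening-risen genes went both ways, 390 higher and 387 lower than the sum of the single changes, and with size factors 300 higher and 477 lower. The ripening-fallen genes comprised 1321 higher and 1233 lower, and with size factors 1014 higher and 1485 lower. Over all genes 12808 departed from the sum, 9044 higher and 3764 lower, and with size factors 5973 higher and 5792 lower, where the median went from 0.36 to 0.028.

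A direct comparison of dml2-3 with the double mutant at 34 dpa gave lower values in dml2-3 for both rising genes. Solyc10g080210.2 differed by -3.31 (SE 0.55, limma adjusted p = 2.22e-05) and Solyc08g066240.3 by -1.26 (SE 0.25, adjusted p = 0.000159), or -2.29 with a pseudocount of 0.1. Solyc07g054310.3 was higher in dml2-3 by 3.94 (SE 0.30, adjusted p = 3.8e-10) and Solyc01g086920.3 by 2.87 (SE 0.53, adjusted p = 7.49e-05). Among the ripening-risen genes 487 were lower and 185 higher in dml2-3 than in the double mutant, and of the ripening-fallen genes 1449 were higher and 1066 lower. In total 11492 genes were called, 4738 higher and 6754 lower. Rescaled to equal totals (TPM), 5903 were higher and 5328 lower.

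Before ripening, at 25 dpa, dml2-3 already differed from WT. Solyc07g054310.3 was at 17.2 ± 3.63 FPKM in dml2-3 and 912 ± 103 FPKM in WT, a log2 difference of -5.66 (SE 0.30, limma adjusted p = 1.92e-12). Solyc01g086920.3 was lower by -4.16 (SE 0.53, adjusted p = 9.74e-07), at 6.70 and 8.34 FPKM in replicates 1 and 2 and 91.7 FPKM in replicate 3. Solyc10g080210.2 was higher by 2.22 (SE 0.55, adjusted p = 0.00173), at 38.8 and 35.3 FPKM in replicates 1 and 2 and 1.99 FPKM in replicate 3. Of the ripening-risen genes 495 were higher and 171 lower than in WT, and of the ripening-fallen genes 2146 were lower and 475 higher. The WT libraries at 25 dpa served both to choose these groups and as the control.

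At 25 dpa 10294 genes were called in dml2-3, 5045 higher and 5249 lower. Without replicate 3, 11916 genes were called and the difference of Solyc10g080210.2 was 3.44, while a fit to the WT and dml2-3 libraries at 25 dpa alone, with all 3 replicates, called 5165 genes and ended the call of that gene (limma adjusted p = 0.165, with 2.39e-17 to 0.165 over the alternatives). Solyc08g066240.3 was at 3.82 ± 2.37 FPKM against 2.14 ± 0.235 FPKM in WT (0.46, SE 0.25, adjusted p = 0.126). It was called with quantile scaling (0.55, adjusted p = 0.0492), and its difference was 0.98 without replicate 3 (adjusted p = 2.06e-08, with 2.06e-08 to 0.555 over the alternatives) but 0.19 without replicate 1 or 2 (adjusted p = 0.555 and 0.551).

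In the double mutant at 25 dpa, both genes with the largest rises in WT were lower than in WT. Solyc10g080210.2 was at 0.0233 ± 0.0404 FPKM (log2 difference -1.78, SE 0.55, limma adjusted p = 0.0156) and Solyc08g066240.3 at 0.0967 ± 0.116 FPKM (-1.52, SE 0.25, adjusted p = 5.5e-05). These differences are on the log2(FPKM + 1) scale, which compresses values this low, and they were -4.44 and -3.66 with a pseudocount of 0.1. The first call ended with quantile scaling (-1.34, adjusted p = 0.0633, and 3.53e-13 to 0.0633 over the alternatives). Solyc07g054310.3 was at 665 ± 60.9 FPKM (-0.45, SE 0.30, adjusted p = 0.278) and Solyc01g086920.3 at 298 ± 14.6 FPKM (-0.16, SE 0.53, adjusted p = 0.848), without a detectable difference from WT. Fitted with the WT and double-mutant libraries at 25 dpa alone, both were called lower (adjusted p = 0.0218 and 0.0483, with 0.0218 to 0.733 and 0.0483 to 0.995 over the alternatives). Among the ripening-risen genes 321 were higher and 92 lower than in WT, and of the ripening-fallen genes 1262 were lower and 386 higher. In total 6183 genes were called, 3290 higher and 2893 lower, and with quantile scaling 4615 were higher and 2621 lower.

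Development within dml2-3 was followed from 25 to 34 dpa. Solyc10g080210.2 fell by 3.51 on the log2 scale (SE 0.55, limma adjusted p = 4.03e-05) and Solyc08g066240.3 fell by 1.60 (SE 0.25, adjusted p = 3.93e-05), opposite to their rise in WT. The second value was -2.64 with a pseudocount of 0.1. In a fit to the dml2-3 libraries alone these calls ended (adjusted p = 0.0957 and 0.0892, with 4.31e-18 to 0.0957 and 4.16e-13 to 0.0892 over the alternatives). Solyc07g054310.3 differed by 0.39 (SE 0.30, adjusted p = 0.346) and Solyc01g086920.3 by 0.41 (SE 0.53, adjusted p = 0.596). The last value was 1.55 without replicate 3 at 25 dpa (adjusted p = 5.15e-08) and -0.24 without replicate 1 (adjusted p = 0.765), and its p ran from 5.15e-08 to 0.919 over the alternatives. Of the ripening-risen genes 72 were higher and 396 lower at 34 dpa, and of the ripening-fallen genes 803 were lower and 485 higher. With size factors the ripening-fallen genes were nearly balanced, at 635 lower and 578 higher, and the ripening-risen genes were 94 higher and 340 lower. In total 6387 genes were called, 2269 higher and 4118 lower, and 8398 without replicate 3. A fit to the dml2-3 libraries alone called 2285. The balance turned with scaling, to 3924 higher and 2627 lower with quantile scaling and 4698 higher and 2109 lower with TPM.

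Development within the double mutant lowered both genes with the largest falls in WT. Solyc07g054310.3 fell by 8.76 on the log2 scale (SE 0.30, limma adjusted p = 2.09e-15) and Solyc01g086920.3 fell by 6.45 (SE 0.53, adjusted p = 1.59e-09). Solyc10g080210.2 rose by 3.79 (SE 0.55, adjusted p = 5.17e-06) and Solyc08g066240.3 by 1.64 (SE 0.25, adjusted p = 9.02e-06), both from below 0.1 FPKM. With a pseudocount of 0.1 these rises were 6.79 and 3.83, so their size rests on the pseudocount. Among the ripening-risen genes 424 were higher and 221 lower at 34 dpa, and of the ripening-fallen genes 1979 were lower and 627 higher. In total 11096 genes were called, 5408 higher and 5688 lower.

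**Figure D4:**
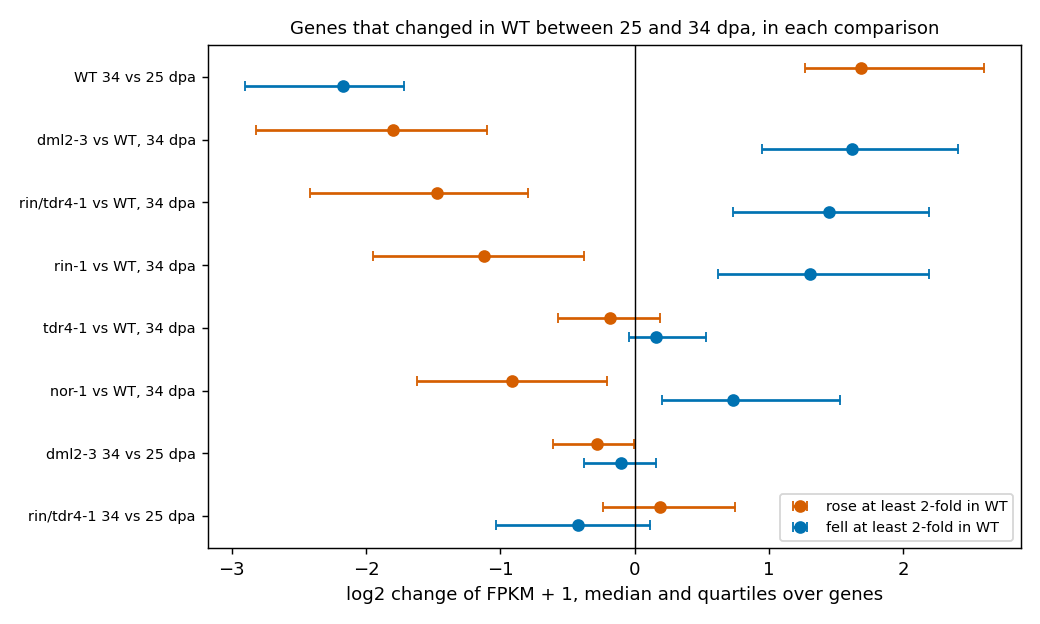
Median (points) and quartiles (bars) of the log2 change of FPKM + 1 over the 1030 ripening-risen and the 3723 ripening-fallen genes in 8 comparisons. In dml2-3 against WT at 34 dpa the medians are -1.80 and 1.62, in tdr4-1 they are -0.18 and 0.16, and within the mutants between stages they lie nearer to 0 than the 1.69 and -2.17 of WT.

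The difference between mutant and WT was then tested for a change with stage. In dml2-3, 999 of the 1030 ripening-risen genes rose less than in WT and 0 more (limma, with 1017 less and 0 more with size factors), and 3552 of the 3723 ripening-fallen genes fell less and 0 more (3468 less and 1 more with size factors). In the double mutant these counts were 895 less and 22 more, and 3315 less and 24 more. Because the groups were chosen on the WT change that enters this test, opposite signs are favoured. Over all genes, the difference changed with stage for 13073 genes in dml2-3, 9858 higher and 3215 lower. With size factors 6688 were higher and 6131 lower, and with quantile scaling 5925 were higher and 6648 lower. In the double mutant it changed for 13306 genes, 10573 higher and 2733 lower. With size factors 6502 were higher and 5850 lower, and with quantile scaling 5509 were higher and 6353 lower. The medians were 0.45 and 0.53, and 0.030 and 0.067 with size factors.

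Over the 14555 genes called in WT, the slope of the stage change in the mutant on that in WT used no library on both axes. In dml2-3 it was -0.0314 (SD 0.055 over 9 pairs of libraries). Without replicate 3 at 25 dpa it was -0.0681 over the same genes, and -0.0729 over the 15203 genes called in WT in that fit. In the double mutant it was 0.193 (SD 0.0025 over 9 pairs). The pairs, of mutant libraries only, reuse the same libraries, so they are not independent and their SD is not a standard error. Of the 2899 genes called higher in WT, 323 were called higher and 918 lower in dml2-3, and 1163 higher and 641 lower in the double mutant. Of the 11656 called lower in WT, 2251 were called lower and 1588 higher in dml2-3, and 4250 lower and 2859 higher in the double mutant. Counts in dml2-3 depended on replicate 3 and on the scaling. Without that replicate, 375 of 3149 genes called higher in WT were called higher and 1387 lower, and of the 12054 called lower in WT 3118 were called lower and 2154 higher. With size factors 1252 of 6759 genes called higher in WT were called higher and 1246 lower, and of the 7354 called lower in WT 1167 were called lower and 1248 higher.

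The responses of mutants at 34 dpa were compared across genes, which are not independent replicates. All share the WT libraries, which alone gave a correlation near 0.50 in 100 simulated sets of unchanged groups. That value holds for groups that differ by noise alone, so it is no baseline for the r of mutants with real differences. The covariance is therefore given beside its simulated value for each pair. The log2 differences of dml2-3 and rin/tdr4-1 correlated at r = 0.74, with a covariance of 1.12 beside 0.0244 in the simulations. The corresponding r was 0.66 for dml2-3 with rin-1 (covariance 0.961, simulated 0.0249), 0.304 with tdr4-1 (0.199, simulated 0.0247) and 0.547 with nor-1 (0.706, simulated 0.0246). The double mutant gave r = 0.579 with rin-1 (covariance 0.766, simulated 0.0247), 0.209 with tdr4-1 (0.124, simulated 0.0246) and 0.421 with nor-1 (0.493, simulated 0.0245). For rin-1 with tdr4-1 r was 0.577 (covariance 0.333, simulated 0.0249). At 25 dpa dml2-3 and the double mutant correlated at 0.309 (covariance 0.149, simulated 0.0245), and at 0.277 without replicate 3 of dml2-3.

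In dml2-3 and the double mutant at 34 dpa, 9052 genes were higher in both and 2085 lower in both. Independent lists of these sizes would share 6604 and 517 genes, and 816 genes were called in opposite directions. With size factors 5013 genes were higher in both against 2654 for independent lists, 4807 lower in both against 2231, and 1083 were opposite. For dml2-3 and tdr4-1, 1851 genes were higher in both against 1454 for independent lists, 1345 lower in both against 771, and 2313 were opposite. For the 2 mutants at 25 dpa, 1499 genes were higher in both against 878, 1571 lower in both against 803, and 982 were opposite. With 3 controls no split keeps 2 libraries on each side, so part of these excesses may come from the shared controls.

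The make-up of the transcript pool also changed between the WT stages. The 100 most abundant genes of each library held 25.3 ± 1.5% of all FPKM in WT at 25 dpa and 42.7 ± 1.8% in WT at 34 dpa (mean ± SD, n = 3, two-sided exact permutation p = 0.1). At 25 dpa it was 29.9 ± 2.0% in dml2-3 and 29.4 ± 0.81% in the double mutant. At 34 dpa this share was 22.7 ± 0.65% in dml2-3, 30.8 ± 0.4% in the double mutant, 39.3 ± 0.47% in rin-1, 46.0 ± 1.4% in tdr4-1 and 40.3 ± 1.4% in nor-1. The exact p against WT was 0.2 for nor-1 and 0.1 for the others. Genes at 1 FPKM or more numbered 17519 ± 37.0 in WT at 25 dpa and 15187 ± 111 in WT at 34 dpa, and 16754 ± 110 in dml2-3, 17013 ± 34.0 in the double mutant, 16557 ± 61.5 in rin-1, 15429 ± 63.1 in tdr4-1 and 16095 ± 15.5 in nor-1 at 34 dpa, each with exact p = 0.1. Groups of 3 against 3 cannot give a p below 0.1, and over the 16 tests of this kind the Benjamini-Hochberg adjusted exact p was 0.107, or 0.2 for the share in nor-1.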

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

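All tests of explanations and of regrouped libraries in this part were chosen after the results were seen, while the tests of a change with stage were planned.

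The difference between dml2-3 and WT changed with stage for 13073 genes, and that between the double mutant and WT for 13306 genes (limma, adjusted over 18906 genes). For Solyc10g080210.2 the change was -14.62 on the log2 scale in dml2-3 and -7.32 in the double mutant, where it was -4.75 with a pseudocount of 0.1. For Solyc08g066240.3 it was -11.18 and -7.94. For Solyc07g054310.3 it was 9.49 in dml2-3 and for Solyc01g086920.3 it was 8.36, while in the double mutant neither was called (adjusted p = 0.488 and 0.0776). The second of these, 1.499 in the double mutant, was called with a pseudocount of 0.1 (2.77, adjusted p = 0.00744), in a fit to the compared groups alone (adjusted p = 6.68e-05), and without replicate 3 of dml2-3 at 25 dpa (adjusted p = 6.8e-07) or without that group (adjusted p = 8.62e-07). Over the 23 alternatives its adjusted p ran from 6.8e-07 to 0.556. Each value is a tested difference between the effects at 2 stages.

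Regrouping the 12 libraries of such a comparison, with 100 groupings drawn, gave as many calls as the real grouping for dml2-3 in 2 of 100 groupings, the real one included, and for the double mutant in 1 of 100. Both shares were under 0.05. The regrouping exchanged genotypes within each stage, so it also broke the plain difference of the mutant from WT. A low share therefore cannot set a change with stage apart from a difference common to both stages. The highest other grouping gave 13230 calls beside the real 13073 for dml2-3, and 13153 beside 13306 for the double mutant. In both, that grouping kept the replicates of every group together and exchanged whole groups, so its many calls point to the structure of the samples.

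The first pattern weighed was that dml2-3 and the double mutant differed from WT at 34 dpa in the same direction across genes. Noise between the shared WT libraries is argued against as the whole cause by the covariance of the log2 differences, 1.12 beside 0.0244 in simulated unchanged groups. The simulations drew only the spread between libraries, so they cannot speak to a deviation common to all WT libraries at 34 dpa. The lower FPKM of most genes in WT at 34 dpa is argued against as the whole cause by size factors, which take out the common shift: 9820 genes were still called in the same direction in both, 5013 higher (2654 for independent lists) and 4807 lower (2231), and without any 1 of the 9 libraries both numbers stayed at least 1.89 times those of independent lists. Over genes called in WT, the mutant stage change had a slope on the WT change of -0.0314 in dml2-3 and 0.193 in rin/tdr4-1. Both mutants thus showed little of the WT stage change over those genes as a set. That this lack underlies the shared direction stays open as a biological hypothesis, which no test here separates from other differences between the genotypes.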

How the results depend on the processing

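The fits without replicate 3 of dml2-3 at 25 dpa, or without that group, in comparisons that do not use it were chosen after seeing the data. Depth is unknown, so its effect on any result was not examined. Tests of gene lists and their alternatives are not reported, since identifiers are not paired with names in the sources used here.

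Counts of called genes stayed within 1.5 times their values under each scaling, pseudocount, filter, variance prior and left-out library, with 2 fits as exceptions. Fitted to the compared groups alone, dml2-3 against WT at 25 dpa gave 5165 genes and dml2-3 between stages gave 2285, and the cause was not tested. Similar counts did not mean the same genes. Between FPKM as deposited and size factors, 1163 genes in WT between stages were called in opposite directions and 10252 in the same direction. At 34 dpa these numbers were 674 and 10599 in dml2-3, 1164 and 9839 in the double mutant, and 30 and 10533 in rin-1. For the double mutant against tdr4-1 they were 1696 and 9669. No gene was opposite in tdr4-1 or nor-1, or in either mutant at 25 dpa. By construction, the requirement of 2-fold change left fewer genes: 6658 in WT between stages, 2606 in dml2-3 and 1140 in the double mutant at 25 dpa, and 6207 in dml2-3, 5993 in the double mutant, 4630 in rin-1, 852 in tdr4-1 and 3440 in nor-1 at 34 dpa. It left 4202 and 6629 for the double mutant against rin-1 and tdr4-1, 5912 for the departure from the sum, 3107 for dml2-3 against the double mutant, 950 and 2499 for dml2-3 and the double mutant between stages, and 6824 and 6661 for the change of their differences with stage.

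The slope of the double mutant was 0.206 with a pseudocount of 0.1 and 0.184 with size factors. With a pseudocount of 0.1, correlations with dml2-3 were 0.727 for the double mutant, 0.665 for rin-1, 0.33 for tdr4-1 and 0.554 for nor-1. Those with the double mutant were 0.6 for rin-1, 0.254 for tdr4-1 and 0.442 for nor-1. That of rin-1 with tdr4-1 was 0.56, and that at 25 dpa was 0.3. With a mean of at least 5 FPKM they were, in the same order, 0.768, 0.678, 0.318, 0.569, 0.6, 0.219, 0.445 and 0.613 at 34 dpa. Without replicate 3 of dml2-3 the correlation at 25 dpa was 0.277. The cause of these shifts was not tested.

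Of 64 results on the 4 genes, 35 kept their direction and their side of the threshold in every alternative run. Over 1136 values under alternatives, 1052 did so, 28 lost the call, 26 gained it and 30 changed sign, each from a value within 0.41 of 0 that was not called. For Solyc07g054310.3, a pseudocount of 0.1 gave 0.22 in the double mutant and 0.18 in tdr4-1 against WT at 34 dpa, and 0.043 in the double mutant against tdr4-1. Size factors gave 0.0044 in tdr4-1, -0.013 in the double mutant against rin-1 and -0.017 in the departure from the sum. Quantile scaling gave -0.045 in the double mutant against rin-1 and -0.29 for the change with stage in the double mutant. For Solyc01g086920.3, TPM gave 0.0072 in the double mutant against rin-1, and quantile scaling 0.012 in the double mutant at 25 dpa.

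Leaving out 1 library moved Solyc07g054310.3 between -0.48 and 0.12 in the double mutant, -0.56 and 0.075 in rin-1, -0.41 and 0.21 in tdr4-1 and -0.16 and 0.44 in nor-1 against WT at 34 dpa. It lay between -0.19 and 0.38 in the double mutant against rin-1, -0.32 and 0.18 against tdr4-1, -0.14 and 0.50 in the departure from the sum, and -0.024 and 0.58 in the change with stage. Solyc01g086920.3 lay between -0.24 and 1.55 in dml2-3 between stages, where replicate 3 at 25 dpa decided, between -0.0026 and 0.31 in tdr4-1, and between -0.29 and -0.057 in the double mutant against rin-1. The cause was not tested.

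Replicate numbers are shared between groups, but same-numbered libraries did not deviate together (pairwise correlations of deviations from -0.138 to 0.1 for number 1, -0.173 to 0.0739 for number 2 and -0.068 to 0.139 for number 3). With the replicate number as a block, 14531 genes were called in WT between stages, 10244 in dml2-3 at 25 dpa, 14161 in dml2-3 at 34 dpa and 14443 in the double mutant at 34 dpa, and no count of calls moved by over 1.5 times.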

Other observations

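The split of WT libraries, all regroupings of libraries and all tests of explanations in this part were chosen after the results were seen, except the test of a mixture, whose prediction was written before its result.

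Of the 1030 ripening-risen genes, 268 were lower than WT in all 5 mutants at 34 dpa under both scalings (133 for independent lists) and 359 in 4 (428), while 29 were lower in none (1). Of the 3723 ripening-fallen genes, 701 were higher in all 5 (349) and 1310 in 4 (1287), while 161 were higher in none (9). The choice of genes and all 5 comparisons use the same WT libraries. In 100 simulated sets with every mutant equal to WT at 34 dpa, and the genes chosen anew, at most 1 ripening-risen gene was lower and at most 1 ripening-fallen gene higher in any mutant. With no mutant difference, adjusted calls were bound to be few, so these sets do not show how the shared libraries act on real differences. How much of the excess over independent lists comes from the shared libraries was not tested. Over these 4753 genes, a slope of -1 of the mutant difference on the WT stage change would put the mutant back at the WT level of 25 dpa. With WT libraries at 34 dpa split so that none entered both axes, the slope ran from -0.800 to -0.791 in dml2-3, -0.674 to -0.660 in the double mutant, -0.598 to -0.589 in rin-1, -0.414 to -0.410 in nor-1 and -0.109 to -0.108 in tdr4-1. WT libraries at 25 dpa entered only the WT change.

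Each comparison of a mutant with WT called some of the 1653 genes not called between WT stages under either scaling. The counts are separate for each mutant and do not show that the same genes differed. Calls were less frequent among these genes than over all genes in every comparison. In the double mutant at 34 dpa, 980 of the 1653 were not called, while 14462 of all 18906 genes were. At 25 dpa 508 were higher and 110 lower in dml2-3 (493 and 101 with size factors), and 147 higher and 59 lower in the double mutant (138 and 53). At 34 dpa the double mutant had 582 higher and 91 lower (366 and 204), rin-1 402 and 99 (347 and 190), nor-1 369 and 172 (387 and 221), and tdr4-1 165 and 70 (200 and 66). In dml2-3 at 34 dpa 386 were higher and 168 lower, but 284 higher and 319 lower with size factors, so the balance there depended on the scaling. All comparisons of a stage share their WT libraries.

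A pattern weighed was that replicate 3 of dml2-3 at 25 dpa stood apart from its group, with r of 0.916 and 0.917. A sample of another group is argued against, since its best correlation with any such library was 0.943, with dml2-3 at 34 dpa, below the 0.981 seen within the other groups. A mixture of dml2-3 RNA at 25 dpa with RNA of another group is argued against, since the best mixture reached 0.945, also below 0.981. That mixture held 94% of dml2-3 at 34 dpa, and the mean of replicates 1 and 2 alone reached 0.918. A difference in developmental stage may contribute and stays open: over the ripening genes, the deviation correlated with the WT stage change at -0.233, between the bounds set for and against it. The stage change of dml2-3 itself hardly followed that of WT (slope -0.0314 over genes called in WT). The correlation therefore cannot decide on a difference in stage within dml2-3. Without this library 11916 genes were called in dml2-3 at 25 dpa and 8398 within dml2-3 between stages, in place of 10294 and 6387.

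The last pattern weighed was that most genes had lower FPKM in WT at 34 dpa, with a median log2 change of -0.513. Unequal column totals are argued against, since equal totals gave -0.562. A few abundant genes taking a larger share could account for most of it: without the 100 most abundant genes at 34 dpa, which held 16.9% of FPKM at 25 dpa and 42.6% at 34 dpa, the median was -0.133. That is not within 0.1 of 0, so a broad fall of transcripts at the breaker stage, a biological explanation that FPKM cannot measure, stays open beside it. The 100 genes were chosen for their level at 34 dpa, which favours a larger share there, so part of the shift may follow from the choice.

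For comparisons of 3 with 3 libraries, the 10 splits of the 6 libraries are too few for a share under 0.05. Every other split mixes the groups compared, so a difference between them enters the spread. Fewer calls there follow from that difference and add no separate evidence. The real split, 1 of the 10, gave 14555 calls in WT between stages (highest other 37). In dml2-3 and the double mutant at 25 dpa it gave 10294 (5127) and 6183 (2). At 34 dpa it gave 14175 (2) in dml2-3, 14462 (1) in the double mutant, 12687 (0) in rin-1, 6840 (6) in tdr4-1 and 11589 (1) in nor-1. The double mutant gave 13146 (1) against rin-1 and 14999 (0) against tdr4-1, and dml2-3 gave 11492 (1) against the double mutant. Between stages dml2-3 gave 6387 (3414) and the double mutant 11096 (1). For the departure from the sum of the single changes, 1 of 100 regroupings, the real one, gave as many as 12808 calls. The highest other gave 9958. These regroupings mixed libraries of genotypes that differed from each other, so fewer calls there cannot set a departure from the sum apart from such differences.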
